A study of Arabidopsis thaliana with 12 samples.

How the data were processed

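RNA from the first leaf pair of Arabidopsis thaliana was sequenced in 12 samples, 3 biological replicates for each of 4 groups, per the labels. The groups were plants on control medium, on 25 mM mannitol (a sugar alcohol used to impose mild osmotic stress), on 0.1 µM NAA (1-naphthaleneacetic acid, a synthetic auxin), and on both compounds. Leaves were taken 10 days after stratification. Libraries were made with a stranded poly(A) mRNA kit, per the labels' protocols. The build was TAIR10, per the submitters' processing notes, and the aligner, the counting method and its strand setting are not given in the sources used here.

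The deposited tables hold 24 columns of counts or normalized values for single libraries. Their headers number the libraries in a way that matches no sample label, and a column can be given to a group only by its label. None of these 24 columns was used. Depth per library, expression levels, replicate spread, fold changes and the direction of any change are therefore not analysed here. The test planned before the data were examined, a quasi-likelihood model on counts for each comparison and for the interaction, was not run. Comparisons of the combined treatment with mannitol or with NAA, the interaction and the correlations between effects were not made for the same reason.

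What was analysed is the authors' deposited table of p-values, with 1 column each for mannitol, NAA and NAA plus mannitol against control, per the file headers. The headers name the values detection p-values. Neither the headers nor the labels say which test produced them, whether they are already adjusted for multiple testing, or whether replicates entered as separate samples. A small p-value here gives neither the size nor the direction of a difference. A listed p of 0 can be a rounded value for any normal z from 8.29 up. Deposited p-values above 0 reach 1.75e-97, 9.98e-123 and 8.36e-288 for mannitol, NAA and both. Genes listed at 0 are thus not known to be more extreme than genes at other very small values.

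The p-values of all 28642 genes were adjusted by the Benjamini-Hochberg method within each comparison, and a gene passed at an adjusted p under 0.05. Adjusted p-values printed for single genes come from this step. Genes at a p of 1 in any comparison could not pass there, so the background for list tests was the 21121 genes with a p under 1 in all 3 comparisons. This also left out genes that passed in another comparison. Of the 2599, 3669 and 7535 genes that passed under mannitol, NAA and both, the background holds 2570, 3668 and 7443. A further 6422 genes had a p of 1 in all 3.

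A set of 30 gene lists with 564 loci was fixed before the data were examined. DAO1, KRP4, UGT75C1 and UGT74C1 were left out because the reference table did not pair their symbol with the listed locus. Of the 560 loci used, 519 were in the background. The reference was TAIR10.1, used only for gene names, product names and gene length, and 28009 of the 28642 identifiers matched it. Each list was tested with Fisher's exact test, two-sided, on passing and other background genes, with Benjamini-Hochberg adjustment over the 29 lists with at least 3 background members. Genes of a list are not independent, and neither a correlation between them nor matching on expression level could be had without library values, so the list p-values are lower than a test with correlation would give if members vary together. The difference of a list between comparisons was tested as the mean difference in percentile of p against 10000 random lists of the same size, with adjustment over 87 tests. Percentiles run from 0 for the smallest p to 100. The smallest p this permutation test can give is 0.0002. Its random lists hold genes drawn at random, so its p does not measure variation between replicates and is too low if members vary together. SAUR, LHCB and RBCS genes have near-identical copies whose reads may have been split, so their values are uncertain.

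The rule for named genes, fixed before the data were examined, had 3 parts. The part on the largest rises and falls could not be applied without fold changes. The part applied to lists names up to 4 members with the smallest adjusted p in a comparison, of which any may be left out. The last part names ERF6, GA2OX6, IAA19, GH3.3 and IAA5 in every comparison.

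The use of Fisher's test on the deposited p-values, the background, all alternatives, 23 families taken from product names and the confidence intervals of odds ratios were chosen after the files were seen, and the intervals after the list results. The alternatives were unadjusted thresholds, adjustment over background genes, Bonferroni adjustment, a reading of each p as a normal z against Student's t with 4 degrees of freedom, leaving out genes at a p of 0, and other list tests. Because the 3 comparisons share control libraries, overlaps were set beside 200000 simulated unchanged genes tested against shared controls with a normal reference. In 3 random draws of simulated p-values for 21121 genes, with 200 changed, the adjustment recovered 99%, 99.5% and 99.5% of genes with a mean z of 6. It recovered 19%, 15% and 16.5% of genes with a mean z of 3. No deposited value entered the draws, so they say nothing on differences between treatments. In the deposited comparisons 2599, 3669 and 7535 genes passed, far more than 200, so the adjusted threshold reached larger p-values there. The simulated shares are thus not the recovery in the data. Unchanged genes were given uniform p-values there. These tests therefore say nothing on false passes if the deposited p-values are too small. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.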

Results

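The study compared first leaf pairs of Arabidopsis seedlings grown on control medium, 25 mM mannitol, 0.1 µM NAA or both, with 3 biological replicates in each of 4 groups. Its title places the question in the interplay of auxin signalling and osmotic stress in leaf growth. The values reported are p-values for 28642 genes in 3 comparisons with control. They carry no direction, size or replicate error, and the depth of each library is not analysed here. A gene is said to pass when its adjusted p was under 0.05.

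The comparison of mannitol with control asked which transcripts differ under mild osmotic stress. The list of ethylene and mild osmotic stress regulators stood out, with 11 of 28 members passing (39.3%, against 12.1% of other genes). Its odds ratio was 4.69 (95% confidence interval 1.98 to 10.6, Fisher's exact adjusted p = 0.00725), and 13 of its 29 listed members passed when adjusted over the list alone. For counts adjusted over a list alone, here and below, no share of other genes was computed. The leading members were transcription factors. ERF98 was listed at a p of 0, and WRKY15 (adjusted p = 6.08e-11), WRKY30 (1.53e-05) and MYB51 (2.97e-05) also passed in the authors' deposited table after adjustment. ERF6, a regulator of leaf growth under osmotic stress, did not pass (adjusted p = 0.746 from the authors' deposited table). GA2OX6, which encodes a gibberellin-inactivating enzyme, did (0.00839 from the authors' deposited table).

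No auxin list passed Fisher's exact test under mannitol, though SAUR genes did by median rank (adjusted p = 0.0435, a permutation test). Of the Aux/IAA repressors 4 of 27 passed, of the SAUR genes 7 of 25, of the GH3 amido synthetases 1 of 7 and of the auxin response factors and receptors 4 of 21. The adjusted list p was 0.376 for SAUR genes and 0.999 for the other 3 lists. IAA14 (adjusted p = 1.24e-08), SAUR67 (1.5e-08), AFB2 (6.56e-07) and the efflux carrier gene PIN7 (5.75e-05) passed in the authors' deposited table after adjustment. IAA19 (adjusted p = 0.495), GH3.3 (0.116) and IAA5 (0.147) did not, from the authors' deposited table after adjustment. Before it, the deposited p was 0.126 for IAA19, 0.0137 for GH3.3 and 0.0189 for IAA5. The abscisic acid and osmotic response list had 3 of 34 members passing, led by ABI1 (adjusted p = 0.000238 from the authors' deposited table), a phosphatase gene of abscisic acid signalling. GRF5, a promoter of leaf cell proliferation, and the pathogenesis-related gene PR5 were listed at a p of 0 in the authors' deposited table. The leaf growth regulator list that holds GRF5 did not pass in any comparison, with 2 of 25 members passing under mannitol, 7 under NAA and 5 with both compounds (Fisher's exact adjusted list p = 0.999, 0.44 and 0.471). PAD3, of camalexin synthesis, passed (adjusted p = 7.17e-11 from the authors' deposited table), with 4 of 13 background members of the salicylate and pathogen defence list. That list did not pass against background genes (Fisher's exact adjusted p = 0.613). With all genes as background and all 16 listed members it did (0.0289). No flavonoid (0 of 16) or jasmonate (0 of 20) member passed.

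In all, 2599 genes passed under mannitol, and 5129 had an unadjusted p under 0.05. When each p was read as a z against Student's t with 4 degrees of freedom, between 0 and 79 genes passed, depending on what a listed p of 0 stands for.

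The comparison of NAA with control asked which transcripts differ under added auxin. The list that passed was glucosinolate synthesis, the pathway of sulfur-containing defence compounds of Brassicaceae. Of its 16 members 9 passed (56.2%, against 17.3% of other genes), with an odds ratio of 6.13 (95% confidence interval 2.03 to 19.4, Fisher's exact adjusted p = 0.0145), and 12 of 17 passed when adjusted over the list alone. CYP83B1 (adjusted p = 4.19e-18), SOT16 (1.43e-13), MAM1 (2.54e-11) and UGT74B1 (3.47e-08) led it in the authors' deposited table after adjustment.

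No auxin list passed under NAA against background genes, while auxin response factors and receptors did with all genes as background (Fisher's exact adjusted p = 0.045). Aux/IAA genes passed in 8 of 27 cases (adjusted list p = 0.44 in Fisher's exact test), auxin response factors and receptors in 8 of 21 (0.279), auxin transport in 6 of 20 (0.44), SAUR genes in 6 of 25 (0.769) and GH3 genes in 1 of 7. Single members passed, among them IAA18 (adjusted p = 2.97e-20), SAUR78 (9.92e-11), the receptor gene TIR1 (4.18e-10) and AFB1 (4.35e-07) in the authors' deposited table after adjustment. AUX1, an auxin influx carrier gene, and CPD, a brassinosteroid synthesis gene, were listed at a p of 0 in the authors' deposited table. The early auxin response genes IAA19 (adjusted p = 0.208), GH3.3 (0.101) and IAA5 (1) did not pass, nor did ERF6 (0.177) or GA2OX6 (1), from the authors' deposited table after adjustment. Before it, the deposited p was under 0.05 for IAA19 (0.0434), GH3.3 (0.0162) and ERF6 (0.0345). It was not for IAA5 (0.773) and GA2OX6 (0.912). If the deposited values were already adjusted, the former were adjusted a second time here. Under NAA 1290 genes lay within 1e-06 of 0.317, the two-sided normal tail of a z of 1. Adjustment for multiple testing would have moved them off that value, which argues against values already adjusted. GRF3 (adjusted p = 1.48e-06), the xyloglucan endotransglucosylase/hydrolase gene XTH4 (4.14e-14) and the stomatal lineage gene SPCH (5.53e-06) passed in the authors' deposited table after adjustment. Of the mitotic cell cycle list 7 of 25 members passed, with CDKB1;2 (adjusted p = 0.00011) the smallest in the authors' deposited table. No cytokinin member of 15 passed.

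Under NAA 3669 genes passed, and 6243 had an unadjusted p under 0.05. The t reading left between 0 and 83.

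Plants on both compounds differed from control in the most genes, 7535, with 9717 at an unadjusted p under 0.05. The list of photosystem and Rubisco genes passed, with 22 of 33 members (66.7%, against 35.2% of other genes), an odds ratio of 3.68 (95% confidence interval 1.71 to 8.42) and a Fisher's exact adjusted p of 0.00972. Adjusted over the list alone, 28 of 33 passed. So did 22 of 29 ethylene and osmotic regulators, a list that did not pass Fisher's exact test with both compounds. PSBP1 (adjusted p = 2.43e-07), PSBO2 (4.22e-06), PSAN (4.73e-06) and RBCS1B (8.2e-05) led the photosystem and Rubisco list in the authors' deposited table after adjustment. With either compound alone 3 of 33 members of the photosystem list passed. The difference in its rank of p between NAA and both compounds did not pass its own test (adjusted p = 0.423 against random lists, a permutation test). By the median rank of its p-values the list itself did not pass (adjusted p = 0.0847, a permutation test on random lists), and glucosinolate synthesis did (0.0116).

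With both compounds, ethylene and osmotic regulators passed in 16 of 28 cases (adjusted list p = 0.158 in Fisher's exact test) and glucosinolate genes in 10 of 16 (0.161). CYP83B1 and SOT16 were listed at a p of 0 in the authors' deposited table. Aux/IAA genes passed in 10 of 27 cases, SAUR genes in 12 of 25 and GH3 genes in 3 of 7, with no list past the threshold. SAUR36, SAUR72 and ARF6 were listed at a p of 0 in the authors' deposited table. GH3.3 (adjusted p = 3.06e-09) and GA2OX6 (0.00737) passed, while ERF6 (0.0825), IAA19 (0.829) and IAA5 (1) did not, from the authors' deposited table after adjustment. Before it, the deposited p was 0.0241 for ERF6, 0.518 for IAA19 and 0.966 for IAA5. The jasmonate synthesis genes AOS (adjusted p = 8.04e-66) and LOX2 (1.71e-35) had the smallest values of their list in the authors' deposited table after adjustment. Of that list 8 of 20 members passed (40%, against 35.2% of other genes), and the list itself did not pass (Fisher's exact adjusted p = 0.892). Expansins and xyloglucan hydrolases passed in 19 of 35 cases (adjusted list p = 0.158), led by XTH4 (adjusted p = 2.99e-43 from the authors' deposited table). The t reading left between 0 and 610 genes.

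Mitotic cell cycle genes were the list whose rank differed between comparisons. Their mean percentile of p was 26.2 under NAA, 37 under mannitol and 68 under both compounds. Both differences from the combined treatment passed (adjusted p = 0.0087 in each, a permutation test at the smallest p it can give before adjustment). With both compounds 3 of 25 members passed, against 35.3% of other genes (adjusted list p = 0.158 in Fisher's exact test). CYCA2;1 (adjusted p = 2.08e-05), CYCA2;3 (0.00185) and CYCB1;1 (0.0409) were those members in the authors' deposited table after adjustment. None of the other differences between comparisons passed among 87 tests, and the next smallest adjusted p was 0.0661, for flavonoid, leaf growth and glucosinolate genes.

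Markers of other cell types and states gave no list past the threshold in any comparison. Root and meristem markers had 0 of 5 and 0 of 3 members passing in each comparison. Vascular markers passed in 0, 1 and 2 of 14 cases under mannitol, NAA and both, heat shock proteins in 0, 1 and 1 of 7, and clock genes in 0, 0 and 1 of 14. Stomatal lineage and guard cell markers passed in 2, 2 and 6 of 11 cases and trichome markers in 1, 2 and 2 of 6. The lists not named above (auxin synthesis, gibberellin, DNA replication, endoreduplication, sugar starvation and brassinosteroid genes) did not pass either, and the LBD list, with 1 background member, was not tested.

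**Figure D1:**
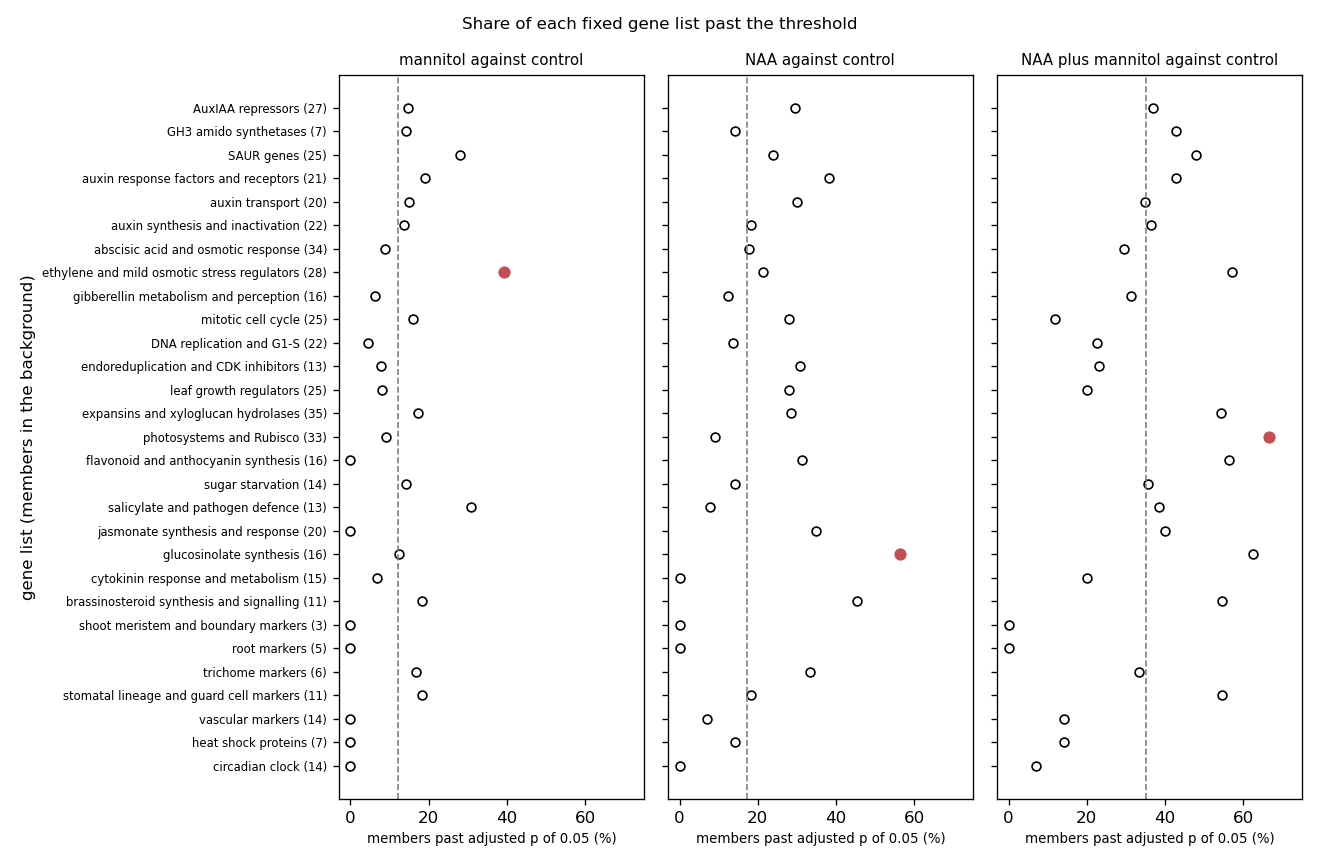
Share of background members of each of 29 fixed gene lists that passed an adjusted p of 0.05 (x axis, %), by list (y axis, number of background members in brackets), for each comparison with control. Dashed lines mark the share of all background genes (12.2% under mannitol and 35.2% with both compounds), and filled points mark the list that passed Fisher's exact test in each comparison.

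Passing genes overlapped between comparisons. Mannitol and NAA shared 1035 background genes, against 446 for independent lists (2.32 times). Mannitol and both compounds shared 1894 against 906 (2.09 times), and NAA and both compounds 2245 against 1293 (1.74 times). Simulated unchanged groups measured against the same controls overlapped 3.62, 3.25 and 3.33 times at the same p limits. Lists of the observed sizes allow at most 5.76, 2.84 and 2.84 times, so the simulated ratio was out of reach for both pairs with the combined treatment and decides nothing there. Across background genes, which are not independent replicates, Spearman's rho of the p-values was 0.317 for mannitol and NAA, 0.408 for mannitol and both, and 0.311 for NAA and both. Simulated unchanged groups gave 0.2, 0.196 and 0.199. The simulation holds no effects and the controls were not split, so how much of the overlap comes from sharing them was not determined. Of the 21121 background genes, 855 passed in all 3 comparisons, and 4159 passed with both compounds and in neither single treatment. Whether the combined treatment differed from each single treatment in those genes was not tested.

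**Figure D2:**
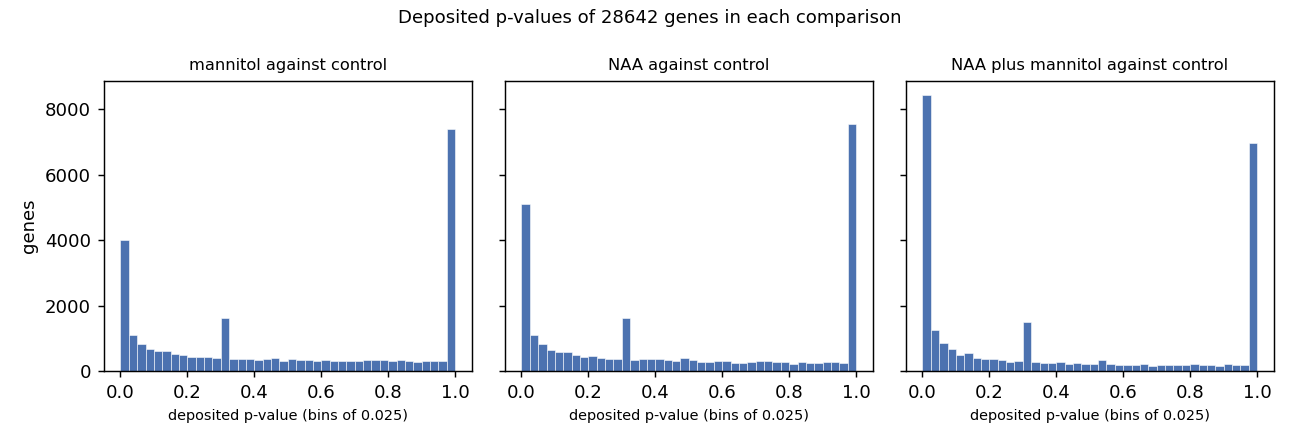
Number of genes (y axis) by deposited p-value in bins of 0.025 (x axis) for each comparison with control, over 28642 genes. The bar at the left end is higher with both compounds than with mannitol or NAA. The bar at the right end includes genes at a p of 1 (7049, 7272 and 6804). The bar near 0.317 includes 1235, 1290 and 1218 genes within 1e-06 of a shared value.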

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

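All alternatives here were chosen after seeing the data. Those planned before (other count models, filters, scalings, depth, leaving out each library, other splits of the samples) need library columns that were not used here, and none was run. No paired analysis was possible because the library columns carry no replicate number that the labels match. The counts of genes depended most on the reference distribution. Read against Student's t with 4 degrees of freedom, 0 genes passed in each comparison after Benjamini-Hochberg adjustment in Python if a p of 0 stands for its lowest z of 8.29, with 2716, 3572 and 6486 genes under an unadjusted 0.05 for mannitol, NAA and both. With a p of 0 at its highest z, 79, 83 and 610 passed, against 78, 74 and 423 genes listed at 0. The count is close to the number at 0 for mannitol and NAA and well above it for both compounds. Bonferroni adjustment left 698, 948 and 2423 genes, and an unadjusted 0.05 gave 5129 for mannitol and 6243 for NAA. An unadjusted 0.01, adjustment over background genes and leaving out genes at 0 kept each count within 1.5 times. The lists that passed did so too at an unadjusted 0.01 and against length-matched random lists. With all genes as background 2 lists passed under mannitol (salicylate and pathogen defence added), 2 under NAA (auxin response factors and receptors added) and 4 under both (ethylene and osmotic regulators, expansins and glucosinolate synthesis added). By median rank 2 passed under mannitol (SAUR genes added) and 3 under NAA (mitotic and expansin lists added), while under both compounds 1 passed, glucosinolate synthesis, and the photosystem list did not (adjusted p = 0.0847, a permutation test). The overlap ratios rose to 4.81 (mannitol and NAA), 4.36 (mannitol and both) and 3.23 (NAA and both) with Bonferroni adjustment. Simulated unchanged groups gave 9.13, 8.7 and 9.16, where the list sizes allow at most 22.3, 8.81 and 8.81. The simulated ratio lay just under that limit for mannitol and both, and above it for NAA and both. An observed ratio could hardly exceed the former and could not reach the latter, so the simulation decides nothing for these pairs. For mannitol and NAA the simulated lists were again smaller than the observed ones, which allows a higher ratio, so it decides nothing there either. The ratios were 9.43 (mannitol and both) and 7.6 (NAA and both) with the t reading at the highest z, a setting that was not simulated. Mannitol and NAA shared 2 genes there, too few for a ratio (0.307 expected). For these rank and t results the cause was not tested. What depth limits is not analysed here.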

Other observations

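The families here were chosen after the spread of p-values had been seen, and the tests on small p-values and on the combined treatment were chosen after their results were seen. The gene length test was not. Arabinogalactan proteins, glycoproteins of the cell surface, passed more often than other genes under mannitol, in 15 of 45 cases (odds ratio 3.62, Fisher's exact adjusted p = 0.00403 over 23 families). Under NAA 14 of 45 passed (Fisher's exact adjusted p = 0.157) and with both compounds 22 of 45 (0.267). Against random lists matched on gene length the excess passed in all 3 comparisons (adjusted p = 0.0046, 0.0207 and 0.0337 for mannitol, NAA and both, a permutation test). By median rank the family passed in no comparison (adjusted p = 0.115, 0.517 and 0.235 for mannitol, NAA and both, a permutation test on random lists). F-box genes passed less often than other genes under NAA, in 18 of 229 cases (odds ratio 0.403, Fisher's exact adjusted p = 0.00108), and with both compounds, in 51 of 229 (odds ratio 0.523, adjusted p = 0.000615). By median rank F-box genes did not pass under NAA (adjusted p = 0.517, a permutation test) and did with both compounds (0.0046). Of 628 listed F-box genes, 229 were in the background. Their median percentile under NAA was 58, the value shared by genes tied at a p of 0.317, so the rank test falls on that tie. With both compounds the median was 65.4, and genes tied at 0.317 stood at 69.9. Expression level was not tested for this family.

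Ribosomal protein and histone genes ranked lower in the mannitol comparison than in the others. Ribosomal proteins had a mean percentile of p of 65.6 under mannitol, 49 under NAA and 45.4 with both compounds, with 6, 13 and 40 of 97 members passing. Histones had 67.2, 47.8 and 48, with 1, 7 and 17 of 43 passing. All 4 differences from mannitol had an adjusted p of 0.00345 over 69 tests, in a permutation test on random lists where each stood at 0.0002 before adjustment, the smallest it can give. The test does not measure variation between replicates, and its p is too low if members of a family vary together. Kinesins had a mean percentile of 42.3 under NAA and 65.1 with both compounds (adjusted p = 0.011, a permutation test), where 3 of 27 members passed (adjusted p = 0.0596 in Fisher's exact test and 0.0184 against length-matched random lists). The gene listed at a p of 0 in all 3 comparisons in the authors' deposited table was ATMDAR2 (AT5G03630), a pyridine nucleotide-disulfide oxidoreductase gene, chosen after its values were seen.

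The first pattern is the 6 list and family tests that passed, which gene length might produce, as longer genes have more reads. Those of F-box genes, under NAA and with both compounds, were deficits, and the others were excesses. How many would pass by chance when members vary together was not tested. Of these tests 100% stayed at p under 0.05 against random lists matched on gene length, which argues against length as the whole cause. In every excess the length-matched lists passed less often than other genes, which argues against length there. The shares were 10.9% against 12.1% for ethylene and osmotic regulators and 9.83% against 12.1% for arabinogalactan proteins. They were 16.2% against 17.3% for glucosinolate synthesis and 31.2% against 35.2% for photosystem genes. Length may add to the F-box deficits (15.1% against 17.5% and 33.3% against 35.4%). Expression level was not tested and stays open, as does a biological difference between treatments.

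The second pattern is the excess of very small deposited p-values. For mannitol, NAA and both, 1235, 1290 and 1218 genes lay within 1e-06 of a single value, 0.317, the two-sided normal tail of a z of 1. In each comparison 0 genes stood at 0.374, the tail of Student's t with 4 degrees of freedom. A z of 1 is what a gene with signal in a single library takes when its spread comes from its own samples. A normal reference on 3 against 3 samples would put 1.77% of unchanged genes under 0.0001 with equal spread and 6.02% if all spread lay in 1 group. The observed shares were 5.64%, 7.82% and 16.9% of genes with a p under 1, 3.19, 4.42 and 9.56 times the first bound and 0.938, 1.3 and 2.81 times the second. Mannitol lay below the second bound at 0.0001 but above it at the other thresholds, with 23.8% against 18.9% under 0.05 and 14.3% against 12.3% under 0.01. Both bounds assume normally distributed values, which were not checked, so how much of the excess may come from the reference stays open in each comparison.

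The third pattern is that both compounds together gave more passing genes than either alone. A smaller spread in the libraries of that group could do this, as could larger or more differences. The ratio of gene counts to the larger single treatment rose from 1.56 at an unadjusted 0.05 to 2.21 at 0.0001, by 1.42 times. Either account raises that ratio, so the accounts cannot be told apart without library values.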
